A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

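Muscle of rainbow trout (Oncorhynchus mykiss) was sampled under control, acute hypoxia and chronic hypoxia conditions, with 3 samples per group and 9 in all. Per the labels' protocols, tissue was frozen in liquid nitrogen, total RNA was isolated with Trizol and libraries followed the usual Illumina procedure. The labels do not say whether the samples of a group came from separate fish, so p-values measure only the spread between these samples, which may be technical. The table used holds columns for the 3 control and 3 acute hypoxia samples. The 3 chronic hypoxia samples were not analysed here, so the comparisons of chronic hypoxia with control and with acute hypoxia, and the overlap of the 2 exposures, were not run. The fit was planned over all 3 groups and was made over the 6 libraries of 2 groups.

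The deposited table gives, per the file headers, a read count and an FPKM value (fragments scaled to gene length and library size) per gene and sample. It also gives the authors' mean FPKM per group, the log2 ratio of those means, a p-value and a false discovery rate. Bowtie2 2.2.8 and TopHat2 2.1.1 are named in the submitters' processing notes; the genome build, the annotation and the counting settings are not given in the sources used here. For nearly all genes, the ratio of deposited count to FPKM changed between samples only with the total counts. Of 42552 rows, 76 carried no gene identifier, being the overflow of long annotation cells, and were left out of library sizes and tests. The 42476 genes comprised 41897 with an NCBI gene number, all found in the RefSeq gene table of assembly USDA_OmykA_1.1, and 579 assembled loci without one. Because the authors' build is not given, no coordinates are printed. In 96 genes the counts were 0 in all libraries while FPKM was above 0, so the deposited counts may be rounded estimates. Symbols are those of the table. The trout genome carries many near-identical duplicate genes, and how reads shared between copies were counted is not given, so values of single copies are uncertain.

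Total counts per sample ran from 16986309 to 23922411. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 23791 genes holding 99.8% of counts. Counts were scaled by the trimmed mean of M-values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and those with an absolute log2 fold change of 1 or more were counted too. Standard errors are the absolute log2 fold change over the square root of the test's F. Levels are TMM-normalised CPM (counts scaled to the library size), as mean ± SD of 3 samples. A count of 0 allows up to 3 counts, 0.127 to 0.172 CPM per sample, for counting error only. With 4 residual degrees of freedom the common biological coefficient of variation was 27.7%. Replicates of a group differed by far more than counting noise (chi-square per gene from 54.3 to 140), so none was counted as a duplicate.

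Gene lists (32, of which 8 hold markers of cell types) were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. All copies of a gene in the duplicated genome are separate members. Transcript-variant endings in descriptions were also removed before matching. Lists with 5 or more tested members were tested with camera (limma 3.58.1, voom values, preset inter-gene correlation 0.01), with an estimated correlation and with fry as alternatives. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom instead of a number set by the genes tested. Its adjusted p can therefore be higher without any correlation between members. KEGG pathways and GO processes of the table with 15 to 300 tested genes were tested likewise. Named genes are, first, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose higher group averaged 5 CPM or more. To these were added the called member with the smallest adjusted p of each list other than the marker lists (2 where 5 or more were called) and the highest expressed tested member of each marker list. The highest expressed copies of hif1a, egln3, vegfa, ldha, pdk2, fbxo32, hsp70 and hmox1 were added whether called or not; hmox1 was below the filter. Copies of a gene are named once, by the smallest adjusted p, unless 2 parts of the rule name different copies. Other names below were chosen after their values were seen.

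On simulated counts for this comparison, with 200 genes changed among 23295 tested, the test recovered 6% of 100 genes changed 2-fold and 78% of 100 changed 4-fold. It made 93 calls, 9 of them false, a larger share than the threshold of 0.05 aims at. The calls on the real data may likewise hold more false ones than that threshold implies. A simulated list of shifted genes passed camera at the preset correlation and an unshifted one did not. Camera with an estimated correlation was not run on them, so it was not shown able to pass a shifted list. These lists held genes simulated independently of each other, so they cannot show how camera at the preset correlation behaves where members correlate. For the ribosomal protein list the estimated correlation was 0.511. Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter, a stricter filter (FPKM of 5 or more in 3 libraries), a replicate block, limma voom with sample quality weights and each library left out in turn. After the data were seen, leaving out both libraries numbered 3 and a skin marker covariate were added, together with a list of liver transcripts. The alternatives written for a table of FPKM alone did not apply, and a fit restricted to the 2 groups compared is the one made.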

Results

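The study set out to find genes tied to the effect of low oxygen on muscle metabolism in rainbow trout. Gene-level RNA-seq counts of 3 control and 3 acute hypoxia muscle samples were compared. Total counts were 21794084, 23922411 and 23461340 for control replicates 1 to 3, and 20209641, 16986309 and 18952313 for acute hypoxia replicates 1 to 3. The 10 most abundant genes took 34.6% to 37.5% of the counts. The first principal component (35.1% of variance) ran from the controls to the acute samples. The second (32.4%) set replicate 3 of both groups apart from the other 4 libraries.

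Acute hypoxia against control asks what differed in muscle with the acute exposure. Group was the only term of the fit, so anything else that differed between the groups, such as sampling time, cannot be told apart from the exposure. The oxygen-sensing gene egln2 (NCBI gene 110503496), a prolyl hydroxylase, went from 2.79 ± 0.392 CPM (SD, n = 3) to 29.3 ± 3.91 CPM (SD, n = 3), a log2 fold change of 3.39 (SE 0.18). The kinase Sik2, the phosphodiesterase pde4ca, the transcription factor klf9, the serine-degrading enzyme Sds and the mTOR inhibitor ddit4 completed the 6 largest rises among genes averaging 5 CPM or more in the higher group. Of 23791 genes tested with edgeR's quasi-likelihood test, 108 were called, 101 higher and 7 lower in acute hypoxia. With a log2 change of at least 1 either way, 100 were higher and 7 lower. The 2 groups did not overlap in any of the 108, which calling on the same values nearly ensures. Of all tested genes 15.6% were separated in this way, where chance gives 10%. At an unadjusted p under 0.05 there were 1292 higher and 1173 lower genes. The number called changed with single libraries: it was 23 without control replicate 1, 29 without control replicate 2, 550 without control replicate 3, 27 without acute replicate 1, 31 without acute replicate 2 and 71 without acute replicate 3. It was 463 with DESeq2 and, in fits added after the data were seen, 772 without both libraries numbered 3 and 290 with a skin marker covariate; without control replicate 3 the balance turned to 161 higher and 389 lower, and 18 of the 108 genes were called in all 6 fits that left out 1 library.

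**Figure D1:**
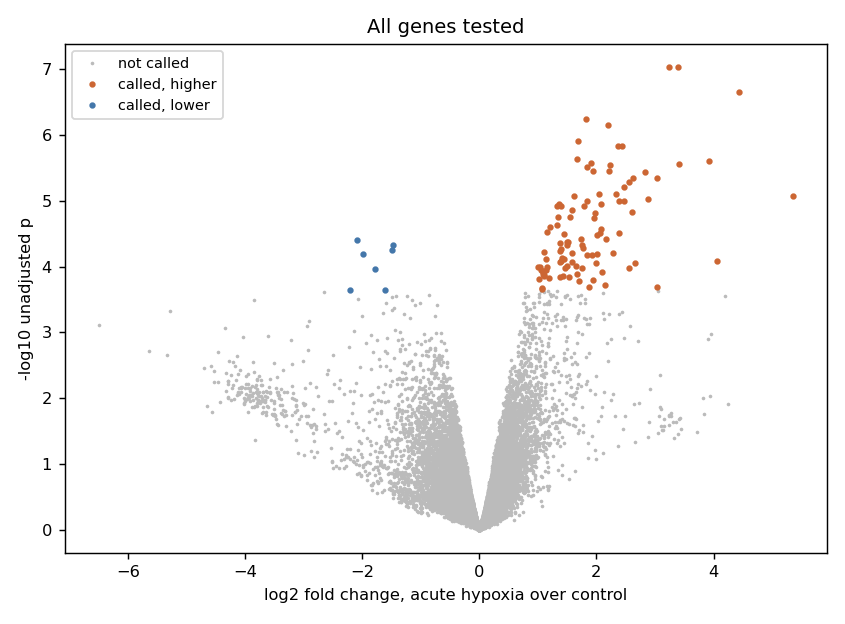
Each point is a gene of the 23791 tested, with its log2 fold change (acute hypoxia over control) on the x axis and −log10 of its unadjusted p on the y axis. The 101 genes called higher lie on the right and the 7 called lower on the left.

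Among the other largest rises, Sds (110525680) went from 0.401 ± 0.0616 to 8.80 ± 2.18 CPM (SD, n = 3 each), and its log2 fold change was 4.43 (SE 0.27). The level of pde4ca (110530132), which breaks down cAMP, was 4.38 ± 0.336 CPM in control and 41.7 ± 6.79 CPM in acute hypoxia. Sik2 (110503529) and klf9 (110525414), a glucocorticoid-induced factor, each had a log2 fold change of 3.04, with an SE of 0.27 and 0.46. All 3 tested copies of ddit4 rose, with log2 fold changes of 2.22 (110531799), 2.38 (118966075) and 5.35 (110530482). The largest falls under the same CPM rule were those of lys (110523157), a lysozyme, from 27.8 ± 12.4 to 5.97 ± 1.57 CPM, and OTUD1 (110535603), a deubiquitinase, from 8.94 ± 2.69 to 2.1 ± 0.289 CPM. Dusp10 (110529423), a phosphatase of stress-activated kinases, Prrt4 (110499878), RFX7 (110526423) and PRKG1 (110498977), the cGMP-dependent kinase, had log2 fold changes of -1.77, -1.62, -1.49 and -1.48. The remaining called fall, Hjv (log2 fold change -1.99), averaged 4.45 CPM in control, below the 5 CPM of that rule. For lys, OTUD1, Dusp10, RFX7 and PRKG1, 1 of 2 tested copies was called. Each of the 6 named falls lost its call in at least 1 fit that left out a library. Of the named genes that were called, ddit4, Sds, egln2, pde4ca, Sik2, Egln3 (110497687), CRY1 and Irs2 were called in all 6 such fits. Copies called in the main fit were 2 of 4 tested for Sik2, 1 of 2 for CRY1 and 1 of 3 for Irs2.

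**Figure D2:**
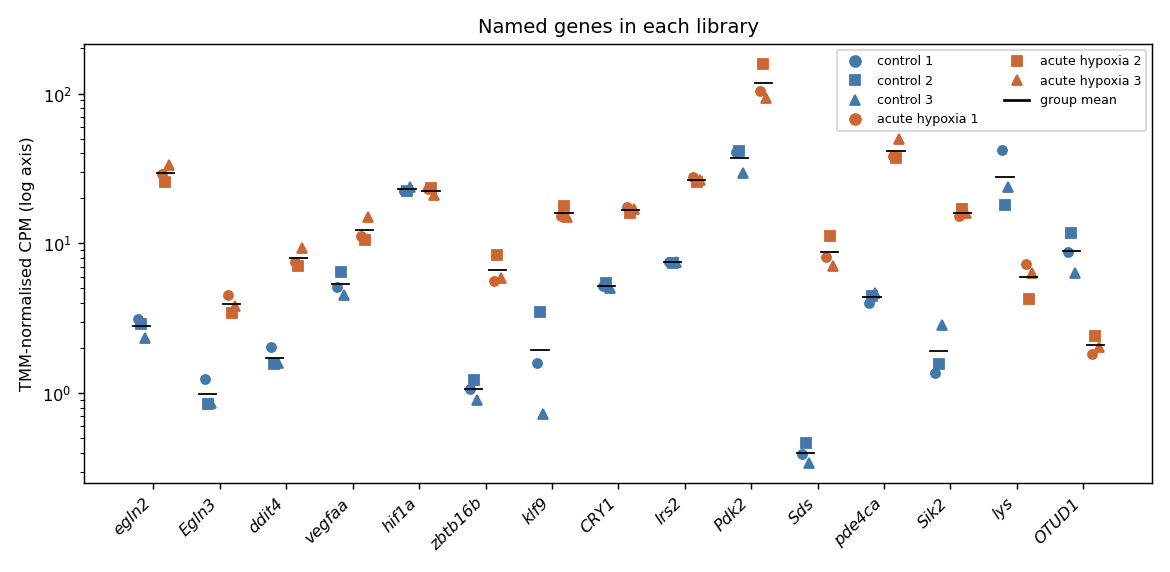
TMM-normalised CPM (log axis) of 15 named genes in each library, with controls in blue, acute hypoxia in orange, marker shapes for the replicate number and black lines for group means. The egln2 points lie near 29.3 CPM in acute hypoxia and 2.79 CPM in control, whereas those of hif1a overlap.

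The list of the hypoxia-inducible factor's subunits, regulators and targets had most calls: 10 of 62 tested members rose and none fell. Adjusted over the list alone, 16 rose and 1 fell. The 10 include 3 copies of ddit4 and 2 each of egln2 and Egln3. Besides egln2, Egln3 (110497687), another oxygen-sensing prolyl hydroxylase, reached a log2 fold change of 3.41 (SE 0.29) from 0.217 CPM, and its more abundant copy (110505778) 2.02. PFKFB4, a regulator of glycolysis, rose by 2.24 and ankrd37 by 2.34 on the log2 scale. The more expressed vegfaa copy (110529696), a vessel growth factor, had a log2 fold change of 1.19 and an adjusted p of 0.0578 by edgeR, so it was not called, and the other copy (110490183) one of -1.07. Transcripts of hif1a (100135944), the oxygen-regulated subunit itself, averaged 22.9 ± 0.781 and 22.5 ± 1.28 CPM. The list passed camera upwards (adjusted p = 8.36e-09), and with an estimated correlation the camera adjusted p was 0.0637. The estimate itself, 0.003, was below the preset 0.01, so correlation between members does not account for the higher adjusted p.

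Of 31 glucocorticoid-responsive genes, 6 were called higher and none lower (12 higher and 1 lower adjusted over the list alone), and 22 had a positive log2 fold change. The transcription factor zbtb16b (110507793) went from 1.06 ± 0.164 to 6.63 ± 1.51 CPM, and Cebpd (100301812) had a log2 fold change of 1.16. The other tested copy of Cebpd was not called. FKBP5, a co-chaperone of the glucocorticoid receptor, rose by 2.56 on the log2 scale, and both called copies of Tsc22d3 by 1.1 and 2.0. The camera test gave an adjusted p of 3.34e-09, and the adjusted p = 0.244 with an estimated correlation. Clock genes had 4 of 62 members called, all higher, and 12 adjusted over the list alone. CRY1 (110494045), a repressor in the clock loop, had a log2 fold change of 1.68 (SE 0.13), the NPAS2 copies 2.06 and 2.62, and Nr1d1 1.40. That list's adjusted p was 3.75e-06, and 0.403 with an estimated correlation.

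Of 54 fatty acid use genes, 5 rose and none fell, and 5 rose and 1 fell adjusted over the list alone. They were pparab (100505415), a nuclear receptor for fatty acids (log2 fold change 1.38), PPARGC1A, ucp2 and 2 of the 3 tested genes with the symbol Pdk2, kinases that restrain pyruvate oxidation. The more abundant Pdk2 (110538080) went from 37.3 ± 6.72 to 118 ± 34.4 CPM. The list as a whole did not pass camera (adjusted p = 0.154). Of 50 glycolysis genes none was called (2 higher adjusted over the list alone), and ldha (110490604), lactate dehydrogenase, averaged 4177 ± 1114 and 2820 ± 959 CPM, overlapping between groups. In the glycogen list 1 of 46 was called, ppp1r3ab (110492867), a glycogen-targeting phosphatase subunit, with a log2 fold change of 1.06, and 3 rose adjusted over the list alone. Neither list passed camera. Insulin and mTOR genes had 2 of 73 called (and 2 adjusted over the list alone), Irs2 (110501605), an insulin receptor substrate, from 7.49 ± 0.0464 to 26.6 ± 0.931 CPM, and irs1 with a log2 fold change of 1.95. That list's adjusted p by camera was 0.00803, and 0.605 with an estimated correlation. With the skin marker covariate the list did not pass camera (0.195), and it passed in the other camera fits at the preset correlation.

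**Figure D3:**
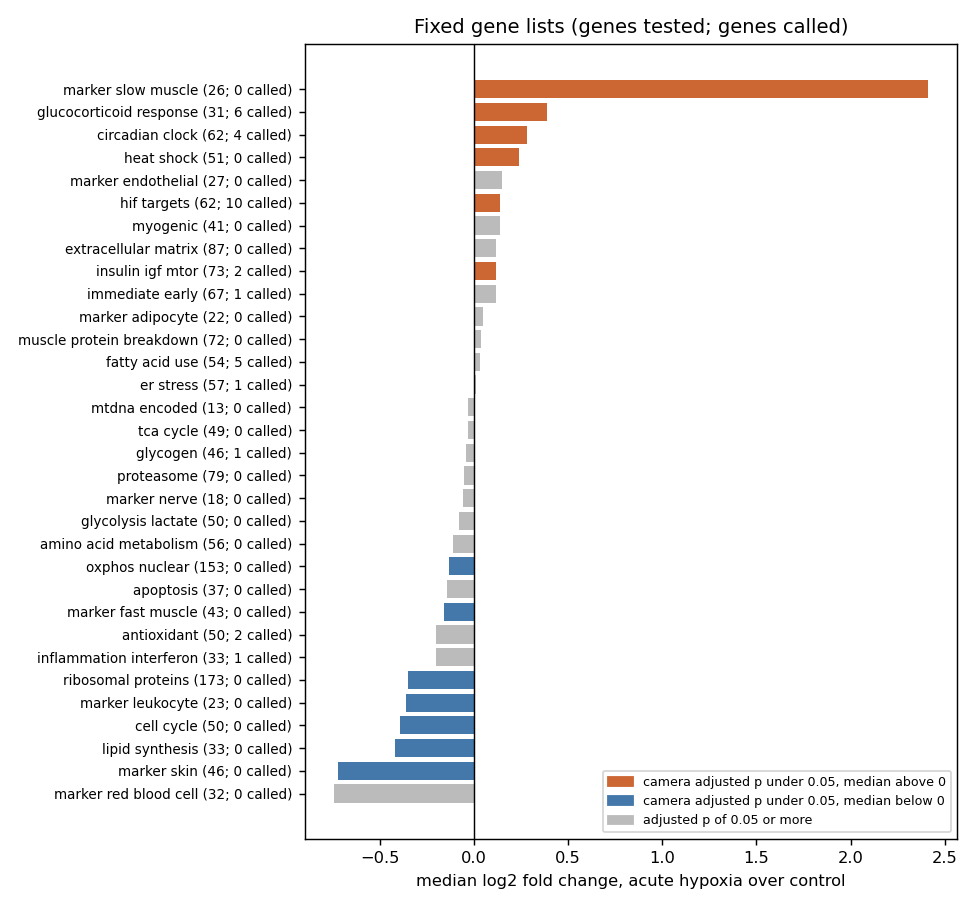
Bars give the median log2 fold change (acute hypoxia over control) of each fixed list, with the tested and called members in its name and colour for lists whose camera adjusted p, at the preset correlation, was under 0.05. The slow muscle markers have the highest median, 2.41, with none called.

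Several lists passed camera at the preset correlation without a called member. Ribosomal protein genes had negative log2 fold changes in all but 10 of 173 members, with a median of -0.35, and an adjusted p of 4.88e-24, which became an adjusted p = 0.605 with an estimated correlation. Lipid synthesis genes (33 tested, median -0.42) had 5 lower and 1 higher adjusted over the list alone, among them the sterol enzymes SQLE (log2 fold change -3.02), hmgcra (-2.20) and dhcr7 (-1.33). Their adjusted p was 0.000187, and 0.403 with an estimated correlation. SQLE (110485563) was at 1.36, 2.11 and 1.88 CPM in control replicates 1 to 3 and at 0.0438, 0.0573 and 0.547 CPM in the acute samples. Its values in acute replicates 1 and 2 lay below the 0.131 and 0.172 CPM that a count of 0 allows there, so the size of its fall is uncertain. Control replicates 1 and 2, where liver transcripts were high, both exceeded the other 4 libraries in 21.2% of the list, against 9.0% of all tested genes. Nuclear genes of oxidative phosphorylation (153, median -0.13) had an adjusted p of 0.000187 and cell cycle genes (50, median -0.39) one of 0.00217, with 0.803 and 0.774 with an estimated correlation. With the skin marker covariate the cell cycle list did not pass camera (0.103). It passed in the other camera fits at the preset correlation that tested it. Heat shock genes (51, median 0.24) had 2 members higher adjusted over the list alone, hspa8b and an hsp70 copy, and an adjusted p of 5.72e-05, or 0.403 with an estimated correlation and 0.0753 with the stricter filter. The most expressed hsp70 copy (118938280) averaged 4.58 ± 1.81 and 4.94 ± 4.78 CPM.

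Stress and atrophy lists held few calls. TXNIP (110496349), which binds thioredoxin, went from 66.1 ± 12.9 to 173 ± 19.9 CPM. It and a further copy (110513274, log2 fold change 1.08) were the 2 antioxidant genes called of 50 (4 higher and 3 lower adjusted over the list alone). Of 4 tested TXNIP copies 2 were called, and no other antioxidant symbol was. The glutathione-degrading chac1 (110522620) was the only endoplasmic reticulum stress gene called of 57 (and 1 higher adjusted over the list alone), at 17.9 and 59.5 CPM. The orphan receptor nr4a1 (110492115) was the only immediate-early gene called of 67 (1 higher and 1 lower adjusted over the list alone), with a log2 fold change of 2.38. Of 4 tested copies of nr4a1, 1 was called. Of 33 inflammation genes nfkbiab (110505735), an NF-kB inhibitor, was the only call (log2 fold change 1.44; list median -0.20, mean -0.88). None of these 4 lists passed camera; without both libraries numbered 3 the antioxidant (adjusted p 0.0469) and inflammation lists (0.00458) passed downwards, and with the skin marker covariate the immediate-early list (0.0139) passed upwards. None of 72 muscle protein breakdown genes was called (camera adjusted p 0.0571), and fbxo32 (100499214), a muscle ubiquitin ligase, had 6.42 ± 1.23 and 18 ± 9.35 CPM with an adjusted p of 0.22 by edgeR. Amino acid metabolism (56 tested, 4 higher and 1 lower adjusted over the list alone), extracellular matrix (87, 1 higher adjusted over the list alone), proteasome (79), tricarboxylic acid cycle (49), myogenic (41), apoptosis (37) and mitochondrially encoded genes (13) had no called member and did not pass camera. The extracellular matrix list (adjusted p 0.0571) passed upwards without a filter (0.0184) and with the stricter filter (6.51e-05). For glycolysis (-0.08 and 0.08), endoplasmic reticulum stress (0.01 and -0.01) and extracellular matrix (0.12 and -0.09) the median and mean differed in sign.

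Markers of other tissues differed between libraries within each group. Slow muscle markers (26 tested, 1 higher adjusted over the list alone, median log2 fold change 2.41, camera adjusted p 0.00217, and 0.774 with an estimated correlation) were high in acute replicates 1 and 2 alone. MYH7, the slow myosin heavy chain, was at 99.3 and 52.9 CPM there, at 1.24 CPM in acute replicate 3 and at 1.86, 1.90 and 10.2 CPM in the controls. The most expressed member, CKMT2 (110523823), averaged 2030 ± 270 and 1626 ± 49.3 CPM. With the stricter filter the slow muscle list turned downwards and did not pass (camera adjusted p 0.657). It passed upwards in the other camera fits at the preset correlation. Skin markers (46, median -0.72, adjusted p 0.00191, and 0.803 with an estimated correlation) were highest in replicate 3 of each group; krt5 (100136029) was at 159 and 55.7 CPM there, against 21.2 and 28.2 CPM in the other controls and 13.3 and 2.87 CPM in the other acute samples. Albumin (alb1, 100499622) was at 974 and 731 CPM in control replicates 1 and 2, at 45.4 CPM in control replicate 3 and at 66.2, 14.6 and 17.8 CPM in the acute samples. The 6 members of the inflammation list that were lower adjusted over the list alone, against 2 higher, were all complement c3 copies, and the most expressed (110489027) was at 386 and 315 CPM in those same controls, 17.7 CPM in control replicate 3 and 31.4, 4.82 and 5.08 CPM in the acute samples. Fibrinolysis genes (23, median -3.56) passed camera downwards with an adjusted p of 0.0211, and an adjusted p = 0.946 with an estimated correlation. None of the 108 called genes belonged to the slow muscle, skin or liver lists.

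**Figure D4:**
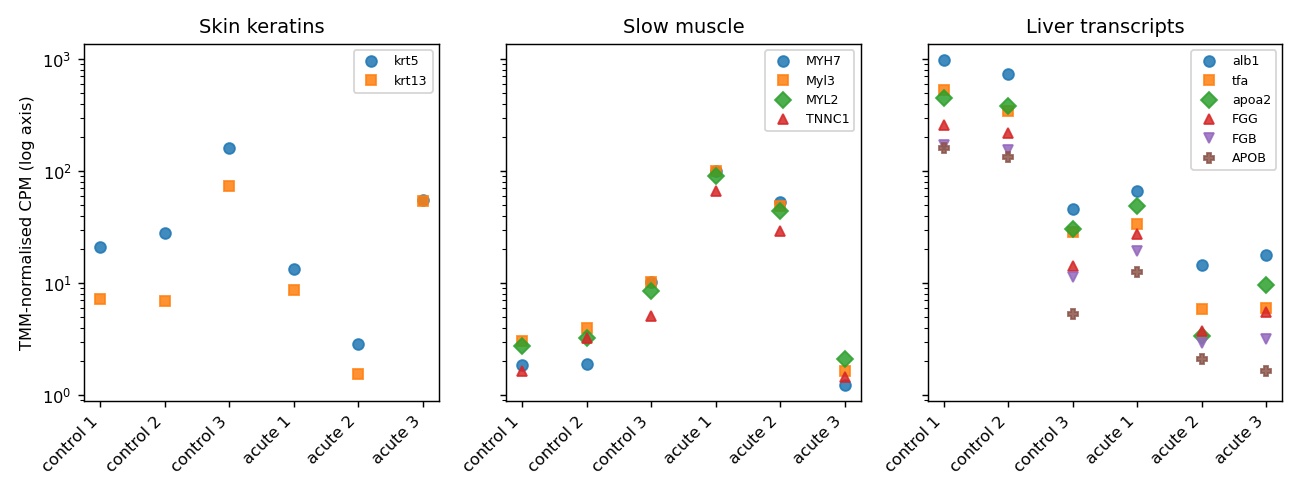
TMM-normalised CPM (log axis) of selected skin keratins, slow muscle transcripts and liver transcripts in the 3 control and 3 acute hypoxia libraries, 1 point per gene and library. The genes drawn were chosen after their values were seen. Other abundant members, such as krt18, CKMT2 and bhmt, differed less between libraries and are not drawn. MYH7 reaches 99.3 CPM in acute replicate 1, krt5 159 CPM in control replicate 3 and alb1 974 CPM in control replicate 1.

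Fast muscle markers (43) had a median of -0.16, a mean of 0.10 and a camera adjusted p of 0.0279 downwards, or 0.774 with an estimated correlation. The list did not pass without a filter (0.144), under the replicate block (0.694) or with the skin marker covariate (0.52). It passed in the other camera fits at the preset correlation. The calcium pump atp2a1l (110491767) averaged 65510 and 56540 CPM. Leukocyte markers (23) had an adjusted p of 0.0456 downwards, or 0.819 with an estimated correlation, with Cd74 (100136156) at 170 ± 93.7 and 133 ± 32.9 CPM. By camera they did not pass without a filter (0.164), without both libraries numbered 3 (0.635) or with the skin marker covariate (0.683). They passed in the other fits at the preset correlation that tested them. Red blood cell (32), adipocyte (22, median 0.05 and mean -0.05), endothelial (27) and nerve markers (18) did not pass. The red blood cell list (median -0.74, adjusted p 0.0677 downwards) passed downwards without a filter (0.0439) and upwards without both libraries numbered 3 (1.63e-05). The markers hbb (110486352), PLIN2 (110500648) and vwf (110502677) had log2 fold changes of -0.87, -0.63 and 0.15, none called.

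Of 5295 annotation terms, camera passed 18 upwards and 60 downwards at the preset correlation and none with an estimated one (adjusted p = 0.946 for each). On 4 degrees of freedom and over 5295 terms the estimated version could hardly pass any term, so its result decides nothing about them. The 5 leading terms downwards were Ribosome (median -0.32), cotranslational protein targeting to membrane, cytoplasmic translation, protein targeting to ER and establishment of protein localization to endoplasmic reticulum, which share the ribosomal genes. Upwards they were amino acid transport (71 genes, median 0.22), platelet-derived growth factor receptor signaling, renal system process, venous blood vessel development and circadian regulation of gene expression, with 8 of 75 called. In the authors' deposited values 452 genes had a false discovery rate under 0.05, 270 higher and 182 lower. All 108 genes called here were among those, with the same sign, and 62 of the 452 were not tested here. The deposited values come from the same 6 libraries, so this is no independent support. Among the named genes the authors' log2 ratios of mean FPKM ran higher, as for egln2 (3.61, against 3.39) and CKMT2 (-0.11, against -0.32). Small fold changes thus depend on the scaling.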

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

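The skin covariate and the fit without both libraries numbered 3 were chosen after the data were seen. All 108 called genes kept their sign in every alternative that tested them, and 10 were called in every one, the stricter filter having removed 58. The count of 108 became 463 with DESeq2 (306 higher, 157 lower), 772 without both libraries numbered 3 (300 and 472) and 290 with the skin score as covariate (174 and 116). Without a filter 15 genes were lower and with sample quality weights 22. Leaving out single libraries gave 23 to 550 genes, 21 to 161 higher and 0 to 389 lower, filtered afresh; on the 23791 genes of all 6 libraries, leaving out control replicate 3 gave 394. Of the 389 genes lower without that library, 50 were on the liver list, as were 52 of the 472 without both libraries numbered 3; the cause was not tested. With the replicate number as a block 446 genes were called, 219 higher and 227 lower; deviations of the same-numbered pairs correlated at 0.20, 0.06 and 0.35, and control replicate 2 correlated best with acute replicate 1 (0.22), so the numbers are not taken to pair the samples. Of 13 lists past the threshold, 0 remained with an estimated correlation, 2 by fry (hypoxia targets, adjusted p = 0.00715, and glucocorticoid response, 0.0354) and 7 with the stricter filter, where 3 (lipid synthesis, cell cycle and leukocyte) could not be tested, heat shock (0.0753) and skin (0.657) were lost, extracellular matrix was gained and the slow muscle list turned downwards (0.657, against 5.18e-21 to 0.774 over all alternatives); the cause was not tested. Without a filter 11 of the 13 remained (fast muscle 0.144 and leukocyte 0.164 lost), under the block 12 (fast muscle 0.694 lost), without both libraries numbered 3 12 (leukocyte 0.635 lost) and with the covariate 8 (insulin 0.195, cell cycle 0.103, fast muscle 0.52, leukocyte 0.683 and skin 0.848 lost). Lists gained were antioxidant (0.00906), inflammation (0.00984), immediate-early (0.0392) and red blood cell (0.0313) under the block, and extracellular matrix and red blood cell without a filter; without both libraries numbered 3 antioxidant and inflammation passed and red blood cell turned upwards (1.63e-05), and with the covariate immediate-early passed. Among genes, signs turned in those not called: hbb (from -1.33 without control replicate 2 to 0.37 without control replicate 3; 0.12 with quality weights, 0.56 without both libraries numbered 3, 0.02 with the covariate), Cd74 (from -0.59 without control replicate 2 to 0.19 without control replicate 3, 0.06 with the covariate), vwf (0.00 without acute replicate 1), hif1a (from -0.04 without acute replicate 1 to 0.02 without acute replicate 3, 0.01 without control replicate 3, 0.05 with the stricter filter, 0.05 without both numbered 3) and hsp70 (-0.44 under the block, -1.12 with quality weights, -0.03 without control replicate 1, -0.06 without control replicate 3, from -0.81 without acute replicate 1 to 0.7 without acute replicate 3, -0.61 with the covariate). Over named genes and alternatives 424 values kept sign and side of threshold. A call was lost in 80, all without 1 library (never control replicate 3), and gained in 8, including vegfaa. Its adjusted p ran from 0.00019 with DESeq2 to 0.304 without control replicate 1. Recovery of 6% at 2-fold in simulated counts limits 3 samples a group. Alternatives for chronic hypoxia or FPKM alone were not run.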

Other observations

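Several called rises, named after their values were seen and forming no fixed list, have a known part in cAMP signalling: 3 copies of CREM, a cAMP-responsive transcription factor (log2 fold changes 2.83, 2.47 and 2.66), the phosphodiesterases pde4ca, pde4ba (1.14) and PDE7A (1.84), 2 copies of Sik2, the receptor adra2b (1.94), and PPARGC1A (1.41). Single called genes also included the transporters SLC43A2 (2.48), Slc43a1 (1.75) and slc7a6 (1.13). The chemokine scavenger receptor ACKR3 rose in 3 copies (1.90, 1.78 and 1.21).

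The test of the duplicate copies and the count of splits were set before their results were seen; the others were chosen after. A wider rise of cAMP-responsive genes was tested with the GO process response to cAMP, 122 genes of which 3 were called higher: camera gave p = 0.0639 at the preset correlation and p = 0.0588 with an estimated one, and the median log2 fold change was 0.03, so the test missed 0.05 and the pattern is not shown to extend to that set. For 49 symbols with a called rise, 84 further tested copies were not themselves called. Their median log2 fold change was 0.14, above the highest of 10000 random sets matched on mean expression (0.13), and 52 of the 84 were positive. Duplicate copies may therefore rise together, although reads shared between near-identical copies may give the same picture and were not tested. The random sets drew genes singly, whereas the 84 copies come from 49 symbols, so the random medians may spread too little. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 108 genes and the highest of the others called 0; 10 splits are too few for a share under 0.05.

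Skin markers were high in control replicate 3 and acute replicate 3. Their median log2 excess over the mean of replicates 1 and 2 was 2.1 in control and 2.42 in acute hypoxia. Skin or mucus cells in those samples may be a source, but this value restates how the pattern was found and leaves that open. A lower share of muscle cells would raise other cell types alike, and the endothelial and nerve medians were at most 0.03, below the lower quartile of the skin markers (0.63), although leukocyte markers were higher in replicate 3 of both groups (1.15 in control, 0.26 in acute hypoxia) and red blood cell markers in that of the controls alone (2.15, against -0.64). The exposure cannot have raised them in control replicate 3, where the lower quartile of the excess was 0.63; in acute replicate 3, whose score of 1.03 lay below the 1.80 of that control, a response stays open.

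Slow muscle markers were high in acute replicates 1 and 2: in 76.9% of the 26 tested, both exceeded the other 4 libraries, against 9.7% of all tested genes. MYH7 and Myl3 reached 99.3 and 99.5 CPM. Slow fibres in those samples may account for this, but the share restates how the pattern was found and leaves that open. A slow-fibre programme raised by acute hypoxia cannot be told apart from it, since 1 acute library, replicate 3, lay at or below the highest control, and 1 library decides nothing.

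Liver transcripts were high in control replicates 1 and 2, on a list drawn up after albumin had been seen there: in 83.8% of 68 tested genes both exceeded the other 4 libraries, against 9.0% of all tested genes. Of the 68, 29 were at 1 CPM or more in all 6 libraries and 2 belong to a fixed list. Alb1, tfa and apoa2 reached 974, 528 and 450 CPM. RNA from liver is a candidate source, but the share restates how the pattern was found, on a list chosen for it, and leaves that open. A fall of these transcripts under acute hypoxia cannot be told apart from it, since 1 control, replicate 3, lay at or below the highest acute library. Red blood cell markers were also uneven, summing to 3050 CPM in control replicate 3 and 402 to 1140 CPM in the other 5 libraries.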
